A study of Caenorhabditis elegans with 4 samples.

How the data were processed

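Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed for DPY-26 in mixed-stage embryos of the wild-type Caenorhabditis elegans strain N2, a mixed male and hermaphrodite population per the labels. The series holds 4 samples, of which 2 are ChIP replicates made with a rabbit polyclonal antibody against DPY-26 and 2 are input DNA. Per the labels' protocols, embryos were fixed in 2% formaldehyde for 30 minutes, chromatin was sheared by sonication, and 2 mg of extract was used for each immunoprecipitation. Libraries were made with single-end adaptors. The labels do not say whether the replicates came from separate cultures, so the spread between them may be technical.

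The files are 3 peak lists in GFF3 format: 1 list for each ChIP replicate and 1 series-wide list that no label ties to a sample. Reads were aligned with BWA, per the submitters' processing notes, which also name the genome build ce10. The lists are on WormBase WS220, per the file headers. The deposited replicate lists name MACS as the peak caller, and the deposited series-wide list names MACS v2. Versions of the aligner and caller, the calling threshold, the use of the input samples and any pooling of reads for the series-wide list are not given in the sources used here. Each peak carries a first base, a last base and a score as the authors' caller gave it. No header or label defines the deposited score or says whether it measures statistical significance or the amount of binding. Its lowest value was 1.3 in the series-wide list, 50.0 in the replicate 1 list and 50.02 in the replicate 2 list. The series-wide list therefore does not share a scale with the replicate lists. Score levels were compared only within a list, and scores of the replicate lists were correlated with each other. The highest score of the series-wide list, 236.34, was shared by 7 X peaks. A score of exactly 3100 was held by 16 replicate 1 and 34 replicate 2 peaks, with 1 higher-scoring peak in each list, so these highest-scoring sites were not ranked among themselves. The files give no read counts or read depths, so the depth behind each peak is unknown. Exact intervals on shares of peaks cover counting error only.

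Lists were compared in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The length of each chromosome was taken as the largest coordinate on it in any list. Comparisons of X with autosomes used the 6 nuclear chromosomes, and mitochondrial peaks were set aside. Shares have 95% Clopper-Pearson intervals. Peak numbers were compared between X and autosomes over complete windows of 1 Mb by a two-sided permutation test (100000 resamples of the window labels), whose smallest possible p is 1e-05. Median scores and widths were compared by a two-sided permutation test over peaks with the same number of resamples. Peaks and windows of a list are not biological replicates, so these p-values describe the lists and not the spread between embryo preparations. The overlap of lists (at least 1 bp) was compared with 9999 circular shifts of the other list within each chromosome, one-sided, whose smallest possible p is 1e-04. Scores of peaks that overlapped one to one between the replicates were correlated on a log10 scale, across peaks.

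The functions were tested on simulated data. For the overlap test, lists made to share 50% of the 1451 replicate 1 X peaks gave 50%. That share was fixed by how the lists were built, so it checks the counting alone. Of 200 unrelated list pairs, 5% had p under 0.05. The unrelated lists held fewer peaks than the replicate 2 X list, placed uniformly at random, and fewer shifts were run. The rate is therefore not shown for lists as dense or as uneven along X as the replicate lists. For the score test, 4% of 100 equal splits of the 858 autosomal series-wide peaks had p under 0.05, and splits set 3 score units apart gave a mean difference of 3.07.

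The comparisons, the alternatives and the rule for named regions were fixed before the data were examined. The rule takes the 10 highest-scoring X peaks and the 10 highest-scoring autosomal peaks of the series-wide list among those overlapped in both replicate lists, plus the highest-scoring such peak of each autosome. The alternatives were each replicate list alone, the highest-scoring 50% and 10% of a list, peaks found in both replicate lists, merging of peaks within 500 bp, windows of 250 kb, leaving out each autosome, other definitions of overlap, and lists of equal peak number. Tests at transcription start sites, of gene lists and of a sequence motif had been planned only for an annotation and genome of the build of the files. The gene table at hand is of another assembly, WBcel235, and coordinates were not moved between builds, so these 3 tests were not run and regions are named by position only.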

Results

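DPY-26 binding was profiled by ChIP-seq in wild-type C. elegans embryos. DPY-26 is a kleisin subunit shared by the mitotic condensin I and by the condensin of the dosage compensation complex, which binds both X chromosomes of hermaphrodites and lowers their transcription. The data comprised 2 ChIP replicates and 2 input samples from mixed-stage embryos of a mixed male and hermaphrodite population, and peak lists were analysed for each ChIP replicate and for the series as a whole. The replicate 1 list held 1725 peaks, the replicate 2 list 3906 and the series-wide list 9365. The read depth behind the lists is unknown, and no values of the input samples were analysed here. All coordinates are on WormBase WS220, and scores are the authors' own value for each peak.

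The first comparison asked how DPY-26 peaks were divided between X and the autosomes. X carried most of the peaks in every list. In the series-wide list, 8498 of 9356 nuclear peaks lay on X, or 90.8% (95% exact interval 90.2% to 91.4%), against 858 on the 5 autosomes together. The share on X was 84.1% in replicate 1 (82.3% to 85.8%) and 93.5% in replicate 2 (92.7% to 94.25%), a mean of 88.8% ± 6.63 (SD, n = 2). X held 480 peaks per Mb in the series-wide list and the autosomes 10.4 peaks per Mb, a ratio of 46.1. The ratio was 24.7 in replicate 1 and 67.0 in replicate 2 (mean 45.8 ± 29.9, SD, n = 2). The direction was therefore the same in both replicates, while the size of the ratio differed by more than a factor of 2.

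The autosomes differed little from each other. Their density in the series-wide list ran from 9.32 peaks per Mb on chromosome V to 11.7 on chromosome III. In replicate 1 it ran from 2.72 on chromosome I to 3.77 on chromosome III, and in replicate 2 from 2.49 on chromosome V to 3.70 on chromosome III. X ranked first of the 6 chromosomes in each list. An exact permutation of the chromosome label cannot give a p below 0.17 with 6 chromosomes, which is the value obtained. Over windows of 1 Mb, the series-wide list had 481 ± 57.9 peaks per window on X (SD, 17 windows) and 10.4 ± 4.70 on the autosomes (SD, 80 windows). The permutation test over windows gave p = 1e-05, its smallest possible value, in the series-wide list and in both replicate lists. The lowest X window held 319 peaks and the highest autosomal window 27.

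**Figure D1:**
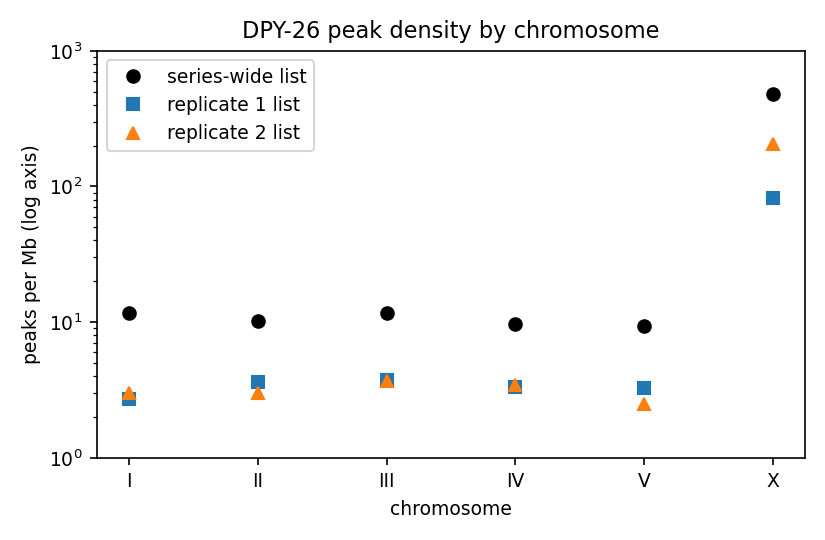
Density of DPY-26 peaks (peaks per Mb, log axis) on each nuclear chromosome, with 1 point for each of the 3 peak lists. X lies at 81.9, 206 and 480 peaks per Mb in the replicate 1, replicate 2 and series-wide lists, and no autosome exceeds 11.7.

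The bases covered by peaks were also mostly on X. Peaks covered 19.0% of X and 0.377% of the autosomes in the series-wide list. They covered 4.66% of X and 0.309% of the autosomes in replicate 1, and 36.9% of X and 0.465% of the autosomes in replicate 2. X thus held 91.5% of the covered bases in the series-wide list, 76.4% in replicate 1 and 94.5% in replicate 2. The covered share of X differed 7.92-fold between the replicates. The replicate 2 list had both more X peaks (3652 against 1451) and wider ones, with a median X peak of 1363.5 bp against 485 bp. Autosomal peak numbers were close, at 274 in replicate 1 and 254 in replicate 2 (264 ± 14.1, SD, n = 2).

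DPY-26 peaks were spread along the whole of X. The left, middle and right parts of X, of equal length, held 2855, 2760 and 2883 series-wide peaks. Neighbouring X peaks were separated by a median of 1097 bp (interquartile range 471 to 2293 bp), and the widest stretch of X without a peak was 24977 bp. The median separation was 6937 bp in replicate 1 and 1840 bp in replicate 2. On the autosomes, the median separation in the series-wide list ranged from 44274.5 bp on chromosome V to 60369 bp on chromosome IV. Over windows of 1 Mb, X peaks were fewest in the first window, with 319, and most numerous in the window that began at 4 Mb, with 549.

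**Figure D2:**
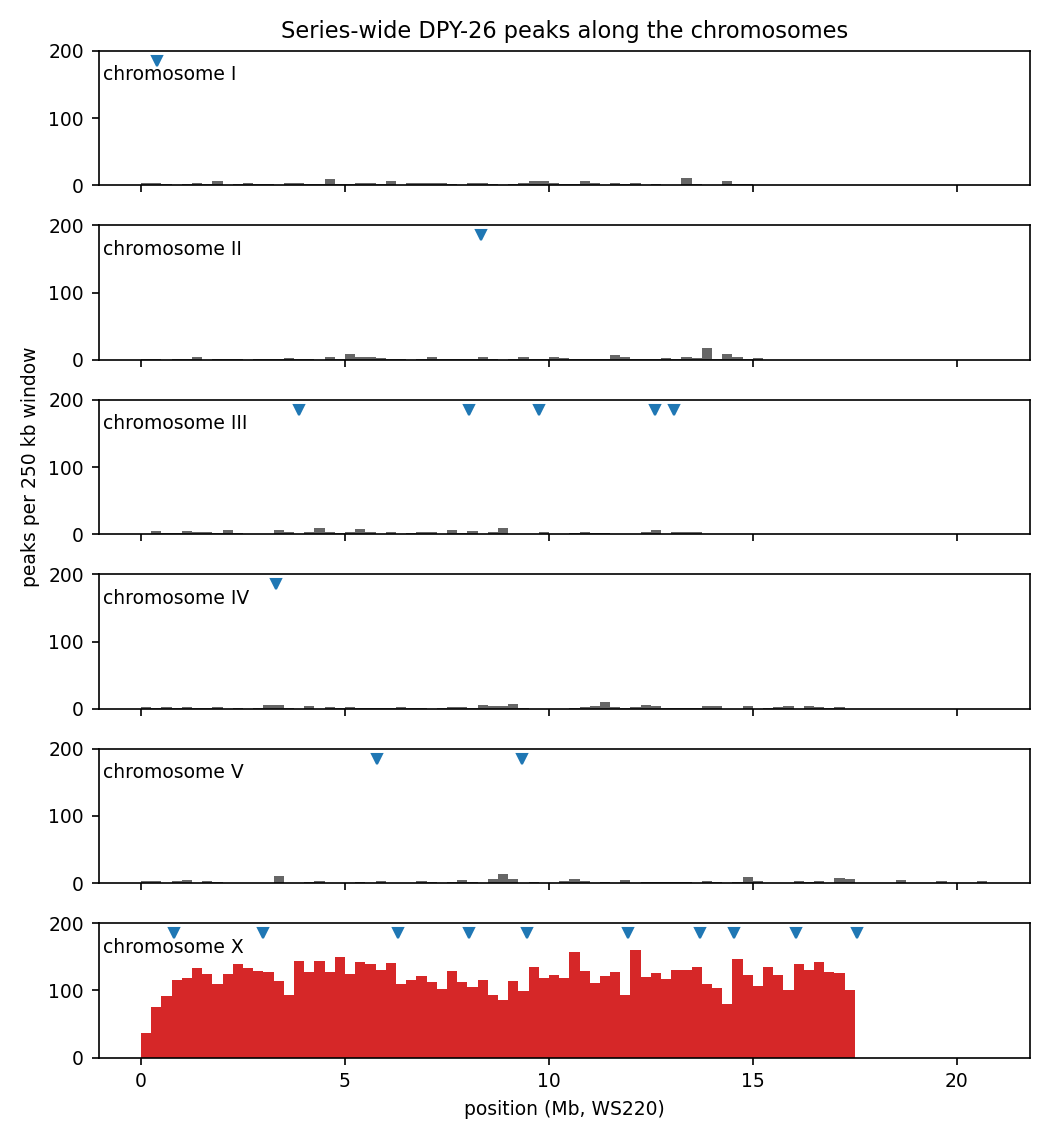
Number of series-wide DPY-26 peaks per 250 kb window (vertical axis, linear) along each nuclear chromosome (horizontal axis, Mb on WS220); bars are windows and triangles mark the 10 highest-scoring X peaks and the 10 highest-scoring autosomal peaks found in both replicates. X windows hold 37 to 160 peaks along its whole length.

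The second comparison asked how peak scores differed between X and the autosomes. The highest-scoring DPY-26 peaks were on X. Whether the score measures statistical significance or the amount of binding is not given in the sources used here, so it ranks peaks within a list and is not read as occupancy. The 100 highest-scoring peaks of the series-wide list were all on X, as were 494 of the top 500 and 975 of the top 1000. The highest autosomal score was 91.0, and 187 X peaks (2.20% of them) exceeded it. A score of at least 20 was reached by 1410 X peaks (16.6%) and by 75 autosomal peaks (8.74%). The 90th percentile of the score was 32.5 on X and 19.4 on the autosomes.

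The typical series-wide peak did not score higher on X. The median score was 6.80 on X (interquartile range 4.37 to 13.6) and 6.89 on the autosomes (4.38 to 11.7), and the difference of -0.09 was not past the threshold (permutation test over peaks, p = 0.74). Among the series-wide peaks found in both replicate lists, the median was 39.7 on X (1340 peaks) and 10.3 on the autosomes (164 peaks), a difference of 29.3. Being found in both depended on the score, and differently so on X and the autosomes (0.747% and 12.9% of peaks with a score under 5, the latter 36 peaks, of which 17 lay in 3 windows of 100 kb). The difference of 29.3 is therefore partly set by the selection, and its permutation test is not taken as evidence of higher X scores. Within each replicate list the X median was also higher. It was 147 against 94.4 in replicate 1 (difference 53.1, p = 1e-05) and 173 against 110 in replicate 2 (difference 62.6, p = 3.2e-04, permutation tests).

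**Figure D3:**
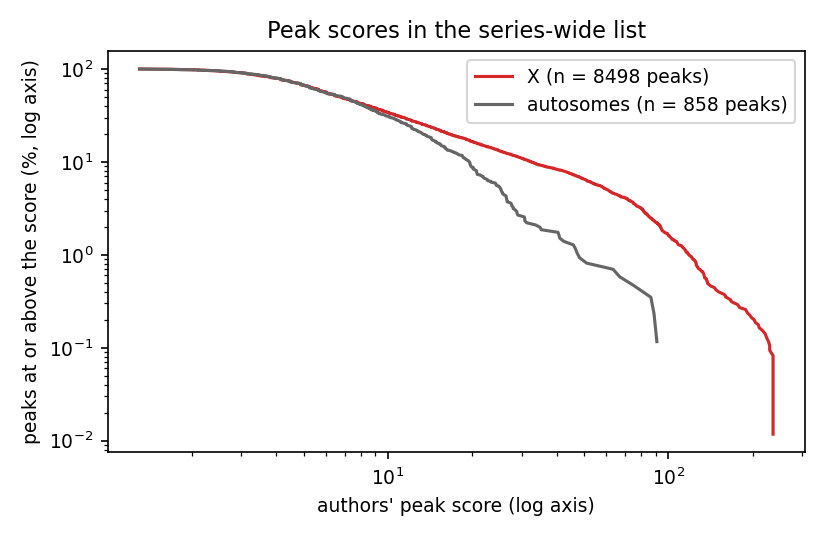
Percentage of series-wide peaks (vertical log axis) at or above a given authors' peak score (horizontal log axis), for X (8498 peaks) and for the autosomes (858 peaks). The curves run together around the medians of 6.80 and 6.89 and part at higher scores, with 16.6% of X peaks and 8.74% of autosomal peaks at 20 or more.

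Series-wide peaks were wider on X, with a median of 304 bp against 248 bp on the autosomes (difference 56 bp, permutation p = 1e-05). Replicate 2 gave the same direction, 1363.5 bp against 1167.5 bp (permutation p = 2.2e-04). Replicate 1 gave the opposite one, 485 bp against 520.5 bp (permutation p = 0.018), so the direction of the width difference did not hold in both replicates. Score and width were correlated across X peaks of the series-wide list (Spearman rho = 0.713, across peaks, which are not independent replicates).

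The 10 highest-scoring X peaks found in both replicates were broad regions dispersed over the chromosome. Of these, 7 shared the highest score, 236.34. They lay at X 2993803 to 2998837, X 8032221 to 8041791, X 9463276 to 9469328, X 11934265 to 11939345, X 13698133 to 13703542, X 14522906 to 14529095 and X 16053192 to 16058253, and were 5035 to 9571 bp wide. The remaining ones lay at X 805308 to 809512 and X 17542884 to 17546802, both with a score of 229.85, and at X 6294904 to 6298837 with a score of 227.39. Each was covered by a single replicate 2 peak with a score of 3100. In replicate 1 the same regions were divided into 2 to 9 peaks, the most at X 8032221 to 8041791, and their best replicate 1 scores ran from 2780.75 to 3100.

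The 10 highest-scoring autosomal peaks found in both replicates were narrower, at 318 to 819 bp. The highest-scoring was at IV 3311000 to 3311642, with a series-wide score of 91.0, 655 in replicate 1 and 966 in replicate 2. It was followed by III 13070242 to 13070860 (score 88.9) and V 5780625 to 5781175 (score 86.7). Among peaks found in both replicates, the highest-scoring of chromosome I was at 382306 to 382695 (score 48.2) and that of chromosome II at 8328900 to 8329217 (score 42.4). A chromosome II peak not found in both replicates had a higher score, 46.6. Chromosome III held 5 of the 10, the others being at 9765286 to 9765747 (75.4), 12608104 to 12608922 (67.0), 8043708 to 8044077 (51.1) and 3867356 to 3867690 (47.3). The remaining peak of the 10 was at V 9343962 to 9344572 (63.6). Each had 1 peak in each replicate list.

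The third comparison asked whether the replicates marked the same sites. On X, 1393 of 1451 replicate 1 peaks overlapped a replicate 2 peak, or 96.0% (94.9% to 97.0%). Because replicate 2 peaks covered much of X, 46.7% were overlapped after circular shifts (central 95% of shifts 44.0% to 49.35%). The observed overlap was 2.06 times that value (permutation by circular shift, one-sided p = 1e-04, the smallest the shifts can give). In the other direction, 1179 of 3652 replicate 2 X peaks overlapped a replicate 1 peak, or 32.3% (30.8% to 33.8%), against 17.1% after shifts (permutation p = 1e-04). With both X lists at 1451 peaks by score, 83.7% of replicate 1 peaks and 69.3% of replicate 2 peaks were shared, against 23.95% and 20.8% after shifts.

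On the autosomes, under 50% of the peaks of each replicate recurred in the other, while shifted lists almost never met. Of 274 replicate 1 autosomal peaks, 123 overlapped a replicate 2 peak, or 44.9% (38.9% to 50.99%), and of 254 replicate 2 peaks, 116 overlapped a replicate 1 peak, or 45.7% (39.4% to 52.0%). After circular shifts the shares were 0.740% and 0.764%, so the observed overlaps were 60.7 and 59.8 times those values (permutation p = 1e-04 for each, the smallest possible). These ratios are high because autosomal peaks are sparse. On X, where 46.7% of replicate 1 peaks were overlapped after shifts, the ratio could not rise far above the observed 2.06. The difference between X and the autosomes itself was not tested. When midpoints within 200 bp were required, 46.6% of replicate 1 X peaks were shared (8.24% after shifts) and 34.7% of autosomal ones (0.122% after shifts). In the other direction the shares were 18.5% of replicate 2 X peaks (3.28% after shifts) and 37.4% of autosomal ones (0.130% after shifts). The scores of peaks that overlapped one to one were correlated between replicates on X (1032 pairs, Spearman rho = 0.770, Pearson r = 0.758) and on the autosomes (111 pairs, rho = 0.481, r = 0.549). These correlations are across peaks, and each of the 4 had a permutation p of 1e-05, the smallest possible, so that the Benjamini-Hochberg adjusted values are also 1e-05. When every overlapping replicate 1 peak was paired with its best replicate 2 score, rho was 0.589 on X (1393 peaks) and 0.490 on the autosomes (123 peaks). The gap between X and the autosomes was smaller under that pairing.

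**Figure D4:**
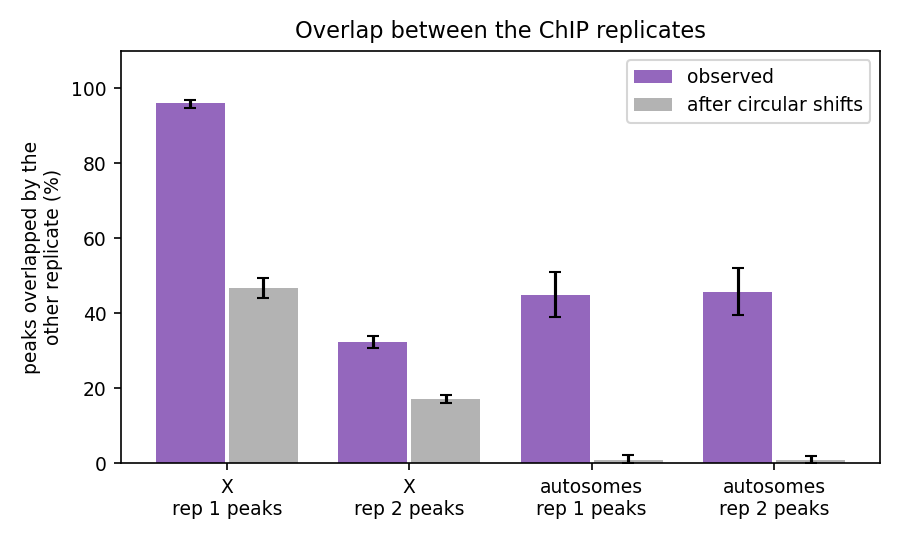
Percentage of the peaks of each replicate (rep) overlapped by at least 1 bp in the other replicate, on X and on the autosomes; purple bars are observed shares with 95% exact intervals, and grey bars are the mean of the circular shifts with their central 95%. Observed shares range from 32.3% to 96.0% and each lies above its shifted value.

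The series-wide list held nearly all replicate X peaks and many more. It overlapped 99.5% of replicate 1 and 98.5% of replicate 2 X peaks, and 80.7% and 90.6% of their autosomal peaks. Of the 8498 series-wide X peaks, 1340 (15.8%) were found in both replicate lists, 4818 (56.7%) in replicate 2 alone, 54 (0.635%) in replicate 1 alone and 2286 (26.9%) in neither. Of the 858 autosomal peaks, 164 (19.1%) were found in both, 144 (16.8%) in replicate 2 alone, 128 (14.9%) in replicate 1 alone and 422 (49.2%) in neither. No circular shifts were run for these shares. Series-wide X peaks lay a median of 1097 bp apart, and replicate 2 peaks covered 36.9% of X against 0.465% of the autosomes. Overlap by position alone is therefore larger on X, and the X and autosomal shares cannot be set against each other. At scores of 50 or more, 536 of 555 X peaks (96.6%) and 7 of 7 autosomal peaks were found in both replicates. Below 5, 0.747% of 2812 X peaks and 12.9% of 278 autosomal peaks were, or 7.31% (4.46% to 11.2%) of the 260 autosomal ones outside the 3 densest autosomal windows of 100 kb, chosen after their values were seen. The X and autosomal shares were 2.48% and 14.3% from 5 to 10, and 14.2% and 24.6% from 10 to 20. From 20 to 50 they were 58.7% (55.3% to 62.0%) and 42.65% (30.7% to 55.2%, 68 autosomal peaks). Below 5, 53.3% of X peaks and 38.5% of autosomal peaks were found in at least 1 replicate.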

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

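The series-wide list held 9 peaks on the mitochondrial genome, which enters no comparison of X with the autosomes. They stood out as a signal outside the nuclear chromosomes, and neither replicate list held any. Their median score was 9.52 (2.98 to 12.3) and their median width 685 bp, and they covered 53.6% of the stretch from base 1490 to base 12693. No biological explanation was tested, and whether the replicate lists had been filtered for this genome is not given in the sources used here.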

How the results depend on the processing

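Of 60 alternative values over 13 results, 52 kept the side of the threshold (or, for values with no test, moved by less than the spread between replicates). That spread comes from the same 2 replicate lists that serve as alternatives. Density ratios of 24.7 and 67.0 thus counted as kept against 46.1, and the count of 52 overstates how stable the sizes were. The excess of X peaks held under every alternative run, with an X share of 84.1% to 97.6% and a permutation p of 1e-05 throughout. The density ratio rose to 193 in the highest-scoring 10% of the series-wide list, where 22 autosomal peaks remained. With each replicate list alone, the X share of covered bases was 76.4% to 94.5%, the median separation of X peaks 1840 to 6937 bp, the X minus autosome difference in median score 53.1 to 62.6, and that in median width -35.5 to 196 bp. The negative width difference was that of replicate 1 alone, and the cause was not tested. The score difference, -0.09 and not past the threshold in the full series-wide list, was positive under each alternative. It passed the threshold of the permutation test in its highest-scoring 50% (2.01, p = 0.0012) and in peaks found in both replicate lists (29.3), both subsets that depend on the score itself, so neither is independent evidence of higher X scores, and did not in its highest-scoring 10% (14.1, p = 0.096) or after merging of peaks within 500 bp (0.54, p = 0.076). The overlap of replicates exceeded that of shifted lists under each definition. No paired analysis was possible because only the ChIP samples had lists of their own, so input and ChIP replicates could not be matched, and leaving out a replicate gives no overlap between replicates. Tests at start sites, of gene lists and of the motif were not run. The unknown read depth limits every count of peaks.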

Other observations

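The tests of peak numbers between the replicates and of whether autosomal peaks cluster were chosen only after the result was seen, as were the counts of peaks near the highest-scoring X sites, the share over clustered peaks that overlap a replicate peak, and the reading of the test at 5 to 20 kb from the highest-scoring X sites.

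Autosomal DPY-26 peaks lay close together more often than random placement gives, although most, 531 of 858, had no other peak within 5 kb. Of the 858 autosomal peaks of the series-wide list, 327 (38.1%) had another peak within 5 kb, against 9.89% after random placement on the same chromosomes (central 95% 7.23% to 12.7%, permutation p = 1e-04, the smallest the placements can give). The densest windows of 100 kb, chosen after their values were seen, were II 13800001 to 13900000 and V 8800001 to 8900000, with 14 peaks each. In both, 13 of the 14 peaks were found in both replicates although their median scores were only 4.88 and 5.45. Replicate 1 held 9 peaks and replicate 2 held 11 in the whole 1 Mb window of V that began at 8 Mb. No 1 Mb window of chromosome II held more than 12 replicate 1 or 11 replicate 2 peaks. In both 100 kb windows, some of the 13 therefore shared a replicate peak. They are not shown to be separate sites that recurred. A group of 11 peaks between V 3434637 and 3440832 was found in both replicates entirely, with a median score of 4.11. A single wide replicate peak could overlap all 11, because the widest chromosome V peaks were 6930 bp in replicate 1 and 7554 bp in replicate 2. The 11 are therefore not shown to be separate sites that recurred. A group of 8 peaks between V 17115415 and 17132102 had a median score of 20.7, yet none was found in both replicates and 6 were in neither. One candidate explanation is that wide regions were cut into several peaks: 170 of the 327 clustered peaks (52.0%, 46.4% to 57.5%) shared a single replicate peak with another series-wide peak, an interval that spans the 50% set as the bound beforehand. However, 101 of the 327 overlapped no replicate peak and so could not share one, and among the other 226 the share was 75.2% (69.1% to 80.7%). Whether wide regions account for most of the 327 stays open, because the 101 could not be judged this way.

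Replicate 2 had 2.52 times as many X peaks as replicate 1 (2.37 to 2.68, counting error only), although autosomal peaks numbered 0.927 times as many (0.778 to 1.10). By number of peaks, the autosomal ratio argues against a more permissive call that adds peaks on all chromosomes alike. For that, at least 1.5 was required, a bound set after the data were seen. However, wider replicate 2 peaks could join neighbours and so lower its count. Peaks covered 0.309% of the autosomes in replicate 1 and 0.465% in replicate 2. Peak number alone therefore does not exclude such a call. Joining in replicate 1 of neighbours that replicate 2 gives apart would place the replicate 2 peaks inside replicate 1 regions. However, 67.7% of replicate 2 X peaks (66.2% to 69.2%) overlapped none, which argues against it as the whole cause. Replicate 1 X peaks were also narrower (median 485 against 1363.5 bp), so this explanation was unlikely from the start. The 10 highest-scoring X regions found in both replicates showed the opposite, each being 1 peak in replicate 2 and 2 to 9 in replicate 1. X peaks of replicate 2 with no replicate 1 counterpart had a median score of 113 against 630 for those with one (difference -516.9, permutation p = 1e-05). Those with a counterpart were also wider (median 1659 against 1254 bp) and so overlap more readily. Peaks that also pass the threshold in a second list are likely to score higher under any of the causes named next. The test therefore cannot single out replicate 2 having reached weaker sites of the same set. Whether a greater read depth, a stronger enrichment or another caller setting lies behind the larger number of X peaks stays open, as does a difference between the embryo preparations. The narrowest peak was 722 bp in replicate 2 and 179 bp in replicate 1.

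The 100 highest-scoring X peaks, called strong sites here for their score alone, were tested for even spacing and for higher scores around them. Their median distance to the nearest other such peak was 44.53 kb, within the 42.3 to 82.3 kb of random picks of 100 X peaks and below the random median of 60.98 kb (permutation p = 0.086). As listed, they were therefore not spread more evenly than X peaks in general. Spacing was not tested on merged peaks, and pieces of a cut-up region among the 100 would shorten these distances. Other X peaks 2 to 10 kb from a strong site did not score higher than those over 20 kb away (difference in medians -0.3, central 95% of circular shifts -0.6 to 0.71, permutation p = 0.28), and with 50 and 200 strong sites, added after seeing the data, the differences were 0.62 (p = 0.16) and 0.08 (p = 0.83). At 5 to 20 kb the difference was -0.42 (central 95% of shifts -0.42 to 0.525, permutation p = 0.052). Because scores were not higher at 2 to 10 kb, there was no excess for shoulders to explain. This test therefore cannot tell whether shoulders of wide regions were cut into separate peaks. The number of X peaks, in contrast to their score, lay above the central 95% of shifts at 5 to 20 kb from 50, 100 and 200 strong sites (675 against 564 to 660, 1239 against 1074 to 1204, and 2233 against 1966 to 2130). At 2 to 10 kb it did so for 50 sites (392 against 312 to 386) but not for 100 (695 against 608 to 698) or 200 (1289 against 1221 to 1354), and cut-up shoulders could add to these numbers. Shifted positions need not fall on a peak, and no random picks of X peaks were compared for these counts. The counts therefore cannot tell whether peaks gather around strong sites more than around X peaks in general.

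The left end of X held few peaks, a feature singled out after its values were seen. The first 250 kb held 37 series-wide peaks against a median of 123 over the 70 such windows of X, 5 against 19 in replicate 1 and 14 against 53 in replicate 2, the lowest count of X in each list. The last complete window of X held 101, 16 and 45 peaks in the same order.

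Several lists had a peak that begins at the first base of a chromosome. These were on I, II, V and X in the series-wide list (scores 25.4, 27.95, 7.43 and 11.4), on I, II, IV and X in replicate 1, and on X alone in replicate 2. The widest autosomal series-wide peak, 11092 bp, lay at I 15060257 to 15071348, ended near the last base of that chromosome in the lists (15072435), and was found in replicate 1 but not in replicate 2.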
